A study of Oryza sativa and Setaria viridis with 38 samples.

How the data were processed

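Leaf poly(A) RNA of a transgenic rice line (Kitaake) and a transgenic Setaria viridis line was sequenced at 5 stages, counted in days after sowing (DAS): 3, 5, 7, 9 and 18 DAS. Both lines carried a yellow fluorescent fusion of the maize plasmodesmata-located protein PDLP1, a marker of the channels between plant cells. Per the labels' protocols, each biological replicate pooled 30 plants grown on Murashige and Skoog medium with 30 g/L sucrose under a 14 h photoperiod at 28 and 24 °C by day and night. Poly(A) libraries were sequenced as 100 bp read pairs. The rice groups held 4 libraries each, and the setaria groups held 3 libraries at 3 and 5 DAS and 4 at the later stages. The protocols also mention a stage before 3 DAS, which was not analysed here.

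Per the submitters' processing notes, reads were handled with Bowtie2, RSEM and DESeq2, and the rice genome was IRGSP-1.0. No tool versions were given in the sources used here. The setaria annotation in the deposited tables names the assembly Setaria_viridis_v2.0. Per the file headers, the deposited per-library values are FPKM (fragments per kilobase of gene, relative to all mapped fragments), although the tables are named as counts. The values carry decimals and no integer counts could be taken from them. The authors also deposited comparison tables with log2 fold changes, p-values and adjusted p-values of DESeq2 for each later stage against 3 DAS. Those tables were read as deposited and set beside the calls made here. One stage code in the files is not a number of days. That code, L3, was taken as 18 DAS because the other 4 stages carry their own numbers. Whether it stands for the same leaf as at the other stages was not tested. The library columns carry codes (such as R4 or R10) that are not, for all libraries, the replicate numbers of the labels, so libraries are named here by stage and code.

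The test chosen from the labels had assumed counts of reads per gene, and it was replaced because the deposited values are FPKM. FPKM were rescaled between the libraries of a species with trimmed means of log ratios, without weights, trimming 30% of log ratios and 5% of mean levels at each end. Genes with at least 0.5 FPKM in at least 3 libraries were kept, which left 27036 rice genes and 23721 setaria genes. Values were tested as log2(scaled FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend. All 5 stages of a species entered one fit, so that the stages shared an estimate of the spread. Fold changes are on this log2(value + 1) scale, which understates the change of low genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels in the text are mean scaled FPKM ± SD over the libraries of a stage, and fold changes carry the standard error (SE) of the fit.

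Gene lists were fixed as search patterns in the description text before the data were examined, as were the stage comparisons of genes, the rule for naming genes and most of the alternatives. Of 36 lists, 34 could be tested in rice and 33 in setaria, where at least 3 members had passed the filter. Each was tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over lists and comparisons. The list tests of 7 with 5 and 9 with 7 DAS were added after the data were seen and adjusted as a family of their own. Camera with an estimated correlation and fry were run beside it. In the 5 comparisons fixed before, 3 of the 79 rice calls and 0 of the 60 setaria calls held with an estimated correlation. Those 3 were aquaporins at 5 and 7 against 3 DAS and chlorophyll biosynthesis at 18 against 9 DAS. In the family of 7 with 5 and 9 with 7 DAS, the call of pectin modification at 7 against 5 DAS in setaria alone held (adjusted p = 0.04). The other list calls below rest on the preset value. In the 5 comparisons fry, which asks whether genes of a list move one way on balance without reference to other genes, called 145 and 96. Between species, FPKM of genes with exactly 1 KEGG orthology number were summed per number, and the difference of the 18 against 3 DAS change was tested with limma over 3888 numbers. The same difference was tested on the mean log2 value of each list per library.

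The genes named are the most abundant members of each list (4 for the plasmodesmata and C4 lists, 3 for the others) and, for each stage against 3 DAS, the 5 called genes with the largest change each way. The latter needed a mean of at least 10 FPKM in the higher stage, no overlap between the libraries of the stages and an informative description. Circadian clock genes, the cysteine-rich repeat secretory proteins and the genes called between 7 and 9 DAS in setaria were chosen after their values were seen.

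The depth of the libraries is not given by FPKM. The steps between low values of short genes (200 to 500 nucleotides) gave relative depths of 0.929 to 1.038 in rice and 0.948 to 1.083 in setaria. The search allowed only limited differences between pairs of libraries, so larger ones could not be found. The deposited FPKM summed to 719230 to 888030 per rice library and 567424 to 717929 per setaria library. No counting intervals could be drawn without counts. The estimated-count method divides reads among near-identical copies, so values of single members of the RBCS, light-harvesting, histone and SWEET families are uncertain. No source stated that strands were told apart, so overlapping antisense genes could not be separated.

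The fit was tested on simulated data with the gene means of the 3 DAS libraries, the spread of each gene within stages and 200 genes changed at 18 DAS. With all 5 stages in the rice fit, 84% of genes raised 4-fold, 38% of genes raised 2-fold, 16% of genes lowered 2-fold and 46% of genes lowered 4-fold were recovered, with 3 of 95 calls false. In the setaria fit these were 60%, 18%, 12% and 46%, with 5 of 73 calls false. With 2 stages alone, 0 simulated setaria changes of either size were recovered, so in this setting many changes of these sizes were missed. Only 200 genes changed in the simulation, while 19182 rice and 13701 setaria genes were called at 18 against 3 DAS. The shares recovered and falsely called depend on how many genes change, so they cannot be carried over to the data. Between 91.4% and 96% of true values lay within 2 SE. The alternatives were another scaling (RLE), no or a stricter filter (at least 1 FPKM), only the libraries of the 2 stages compared, each library left out in turn and, chosen after seeing the data, a pseudocount of 0.1, FPKM as deposited without further scaling, and pairs of libraries left out. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 made the tables and plots.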

Results

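The series followed leaf development in rice, a grass with C3 photosynthesis, and Setaria viridis, a grass with C4 photosynthesis, in lines made to study how plasmodesmata form. The data held 20 rice libraries and 18 setaria libraries, each from a pool of 30 plants. Rice stages had 4 libraries each. Setaria stages had 3 libraries at 3 and 5 DAS and 4 libraries at 7, 9 and 18 DAS, and these are the n behind every mean ± SD below. Between 17583 and 22380 genes reached 1 FPKM in a rice library and between 16240 and 18661 in a setaria library. Libraries of the same stage correlated across genes at 0.87 or above in rice and at 0.857 or above in setaria. Rice libraries at 9 and 18 DAS correlated with those at 3 DAS at 0.506 to 0.626. The later setaria stages were not as well separated, with correlations of 0.793 to 0.966 between 7 and 9 DAS and 0.885 to 0.928 between 9 and 18 DAS. The 7 DAS libraries R9 and R10 correlated with 9 DAS at 0.941 to 0.966. With R1 and R3 of their own stage they correlated at 0.857 to 0.902. Coordinates are those of IRGSP-1.0 for rice and Setaria_viridis_v2.0 for setaria.

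The first comparisons asked what changed in rice leaves between 3 DAS and 5 or 7 DAS. Many genes of light harvesting, secondary wall cellulose and lignin rose, while a pyruvate decarboxylase gene and a haemoglobin gene were among those with the largest falls. Pyruvate decarboxylase 1 (pdc1, Os05g0469600), the entry enzyme of ethanol fermentation, fell from 366 ± 307 at 3 DAS to 2.64 ± 3.83 at 5 DAS, a log2 fold change of -6.80 ± 0.51 (SE; limma adjusted p = 2.52e-08). An ethylene-response transcription factor gene (Os07g0674800) fell from 236 ± 139 to 4.12 ± 2.60, and the early nodulin gene OsENOD93 (Os06g0141600) from 139 ± 21.1 to 2.44 ± 2.35. At 7 DAS the non-symbiotic haemoglobin gene HB2 (Os03g0226200) had fallen from 1023 ± 341 to 10.5 ± 4.43 (log2 -6.49 ± 0.79, limma adjusted p = 3.4e-06). Among genes that rose, the xyloglucan endotransglucosylase gene OsXTH20 (Os10g0545500), a wall-loosening enzyme, went from 0.999 ± 1.14 to 76.8 ± 21.9 at 5 DAS. The abscisic stress-ripening gene OsASR5 (Os11g0167800) went from 21.7 ± 24.7 to 699 ± 248. At 7 DAS a germin-like gene (GLP8-4, Os08g0189300) had risen from 4.77 ± 8.62 to 644 ± 265, and the BURP domain gene OsBURP17 (Os11g0170900) from 0.467 ± 0.604 to 370 ± 137.

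Of the 22 tested light-harvesting genes, which encode the chlorophyll-binding antenna, 18 rose at 5 DAS (18 adjusted over the list alone), with a median log2 change of 2.68. One of them, LHCB (Os03g0592500), rose from 140 ± 25.8 to 2104 ± 252 (log2 3.91 ± 0.94, limma adjusted p = 0.00428). Camera called the list at an adjusted p of 2.11e-05, and the call was lost (adjusted p = 0.136 with an estimated correlation). All 3 tested secondary wall cellulose synthases rose at 5 and at 7 DAS (3 adjusted over the list alone at each). CESA7 (Os10g0467800) went from 1.83 ± 0.751 to 48.8 ± 2.95 at 7 DAS, and the list had adjusted p = 2.44e-05 by camera and adjusted p = 0.0953 with an estimated correlation. Of 75 lignin biosynthesis genes, 36 rose and 5 fell at 5 DAS (40 and 5 adjusted over the list alone; camera adjusted p = 6.22e-06, adjusted p = 0.155 with an estimated correlation). Of 26 aquaporin genes, which encode water channels, 15 rose and 2 fell at 5 DAS (16 and 2 adjusted over the list alone), and camera called this list also with an estimated correlation (adjusted p = 0.0385). Of 31 core histone genes, 11 rose and 1 fell at 5 DAS (15 and 1 adjusted over the list alone; camera adjusted p = 0.0061, adjusted p = 0.496 with an estimated correlation). Of the 13 cysteine-rich repeat secretory protein genes, a family chosen after its values were seen, 2 rose and 7 fell at 5 DAS, among them Os08g0136300, which fell from 226 ± 229 to 2.51 ± 1.5.

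Lists of genes of seed tissue also moved between 3 and 5 DAS, together with the falls of pdc1 and OsENOD93. Of 65 seed storage and late embryogenesis genes 10 rose and 21 fell (12 and 24 adjusted over the list alone; camera adjusted p = 0.0061, adjusted p = 0.305 with an estimated correlation). Of 13 genes found by the alpha-amylase search 1 rose and 6 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.0353, adjusted p = 0.221 with an estimated correlation). Those that fell were the starch-degrading alpha-amylase genes AMY1A (Os02g0765600), Os04g0403300, Os08g0473900 and Os08g0473600, the alpha-amylase inhibitor gene OsPR5 (Os03g0661600) and the peamaclein gene GASR1 (Os03g0760800), and all but GASR1 and Os04g0403300 were chosen after their values were seen. At 7 against 3 DAS camera called neither list (adjusted p = 0.36 and 0.299).

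In all, 4417 rice genes were higher and 3066 lower at 5 than at 3 DAS, and 5305 were higher and 4078 lower at 7 than at 3 DAS. Between 5 and 7 DAS 1147 were higher and 609 lower. The share of calls that were higher at 5 DAS was 59.0%, and 43.3% on the FPKM as deposited, with 4616 genes lower. The 609 genes lower at 7 than at 5 DAS became 385 without the 5 DAS library R1 and 391 with a pseudocount of 0.1. With only the 2 stages fitted 2925 genes were higher and 2174 lower at 7 than at 5 DAS.

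The next comparisons set rice leaves at 9 DAS against 3 DAS and against the neighbouring 7 DAS. Genes of photosynthesis rose, and genes of cell division, DNA replication, cytosolic ribosomes and wall expansion fell. RBCS (Os12g0274700, chromosome 12, 10080508 to 10081440), a gene for the small subunit of the carbon-fixing enzyme Rubisco, rose from 38.0 ± 18.6 to 114515 ± 18021 (log2 11.66 ± 0.36, limma adjusted p = 5.21e-15). The chloroplast carbonic anhydrase gene BETACA1 (Os01g0639900) rose from 23.0 ± 8.57 to 17963 ± 5512, and the Rubisco activase gene OsRcaII (Os11g0707000), whose product keeps Rubisco active, rose from 34.7 ± 17.5 to 18631 ± 9219. The aquaporin gene OsPIP2 (Os09g0541000) rose from 0.091 ± 0.064 to 946 ± 160, and the laccase gene OsLAC8 (Os01g0850700) from 0.25 ± 0.272 to 693 ± 74.3. All 22 light-harvesting genes rose (22 adjusted over the list alone), with a median log2 change of 6.67, and LHCB (Os03g0592500) reached 23556 ± 8103 (log2 7.31 ± 0.94, limma adjusted p = 1.28e-06). Of 43 photosystem subunit genes 39 rose and 1 fell (39 and 1 adjusted over the list alone), and of 36 plastid ribosomal protein genes 30 rose and 6 fell (30 and 6). Of 22 Calvin cycle genes 16 rose and 4 fell (16 and 4), and of 19 chlorophyll biosynthesis genes 16 rose and 3 fell (16 and 3). Camera gave these 5 lists adjusted p of 9.92e-08, 1.22e-12, 9.92e-08, 3.8e-05 and 0.000228 in that order. In the same order, each call was lost, at adjusted p = 0.0953, adjusted p = 0.0953, adjusted p = 0.224, adjusted p = 0.232 and adjusted p = 0.0953 with an estimated correlation.

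Genes of cell proliferation stayed high up to 7 DAS in rice and were low from 9 DAS on. Of 20 mitotic cyclin and CDKB genes 15 fell and 3 rose between 3 and 9 DAS (15 and 3 adjusted over the list alone; camera adjusted p = 4.48e-05, adjusted p = 0.115 with an estimated correlation). CDKB (Os01g0897000), a kinase of the G2 to M transition, fell from 67.0 ± 4.91 to 3.95 ± 0.715. Of 38 DNA replication genes 25 fell and 10 rose (26 and 10 adjusted over the list alone; camera adjusted p = 0.00402, adjusted p = 0.208 with an estimated correlation). OsPCNA (Os02g0805200), the sliding clamp of DNA polymerase, fell from 130 ± 18.9 to 5.61 ± 0.707 (log2 -4.30 ± 0.16, limma adjusted p = 7.85e-14). Of 140 cytosolic ribosomal protein genes 130 fell and 4 rose (131 and 4 adjusted over the list alone; camera adjusted p = 2.28e-18, adjusted p = 0.266 with an estimated correlation). The L36a gene (Os07g0523700) fell from 1923 ± 314 to 570 ± 106. The list meant for plastid-encoded transcripts held 4 genes, which are described as 60S or nuclear-encoded mitochondrial ribosomal proteins, so it gives no measure of RNA quality. All 4 fell (4 adjusted over the list alone; camera adjusted p = 0.0177, adjusted p = 0.302 with an estimated correlation). Of 31 core histone genes 25 fell and 3 rose (25 and 3 adjusted over the list alone), and of 17 YABBY and growth-regulating factor genes of the leaf primordium 15 fell (15 adjusted over the list alone). Their camera adjusted p were 5.92e-05 and 1.51e-06, and both calls were lost, at adjusted p = 0.316 and adjusted p = 0.0953 with an estimated correlation. Of 38 expansin genes, which loosen walls, 23 fell and 3 rose (23 and 3 adjusted over the list alone; camera adjusted p = 0.000828, adjusted p = 0.208 with an estimated correlation). HB1 (Os03g0233900), a further non-symbiotic haemoglobin gene, fell from 567 ± 157 to 0.337 ± 0.274.

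In limma's fit 9672 rice genes were higher and 10354 lower at 9 than at 3 DAS, and 8963 were higher and 10135 lower at 9 than at 7 DAS. On the FPKM as deposited the fold changes at 9 against 3 DAS were shifted by a median of -0.863 on the log2 scale, the share of calls that were higher dropped from 48.3% to 26.9%, with 5500 genes higher, and 588 calls took the opposite sign. The direction of the lists described above did not turn. For 9 against 7 DAS the shift was -0.822 and the share went from 46.9% to 22.5%, with 4400 genes higher.

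**Figure D1:**
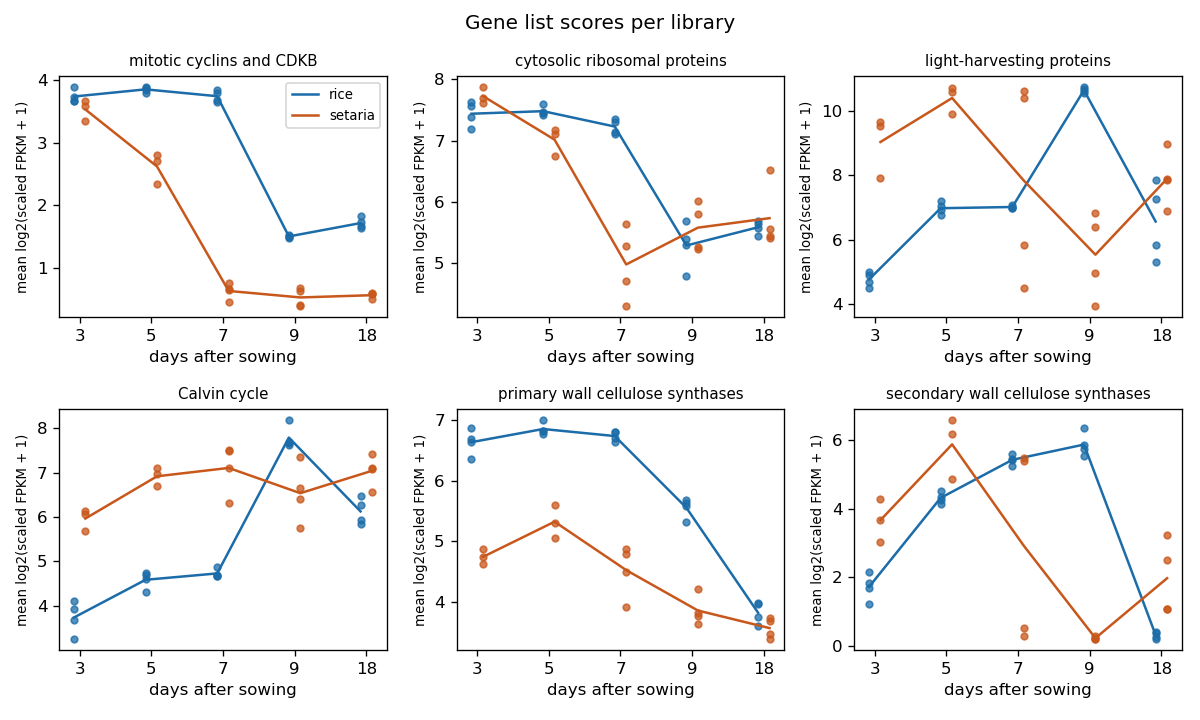
Mean log2(scaled FPKM + 1) over the members of 6 gene lists (vertical axes) by stage in days after sowing (horizontal axes, stages evenly spaced) in rice (blue) and setaria (orange). Each point is a library and each line joins the stage means. The light-harvesting score of the rice libraries lay between 4.483 and 4.995 at 3 DAS and between 10.556 and 10.75 at 9 DAS, and at 7 DAS the setaria libraries R1 and R3 stood at 10.621 and 10.398 while R9 and R10 stood at 4.495 and 5.836.

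Much of the photosynthetic and wall expression gained by 9 DAS stood lower in the rice leaves of 18 DAS. RBCS (Os12g0274700) fell from 114515 ± 18021 to 12057 ± 5310 (log2 -3.36 ± 0.36, limma adjusted p = 4.45e-07) but stayed above 3 DAS (log2 8.30 ± 0.36). LHCB (Os03g0592500) fell to 1825 ± 2126 (log2 -5.38 ± 0.94, limma adjusted p = 0.000131). Of the 22 light-harvesting genes 19 fell between 9 and 18 DAS (19 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.62e-07, adjusted p = 0.0953 with an estimated correlation). Of 36 plastid ribosomal protein genes 29 fell and 4 rose (29 and 4 adjusted over the list alone; camera adjusted p = 1.44e-14, adjusted p = 0.121 with an estimated correlation). Of 19 chlorophyll biosynthesis genes 15 fell and 2 rose (15 and 2 adjusted over the list alone), a call that held with an estimated correlation (adjusted p = 0.0385). All 3 secondary wall cellulose synthases fell (3 adjusted over the list alone), and CESA7 (Os10g0467800) went from 50.1 ± 12.5 to 0.151 ± 0.132. The list had adjusted p = 2.44e-05 by camera and adjusted p = 0.0953 with an estimated correlation. Against 3 DAS, all 6 primary wall cellulose synthases were lower at 18 DAS (6 adjusted over the list alone; camera adjusted p = 0.012, adjusted p = 0.0953 with an estimated correlation), among them OsCesA1 (Os05g0176100), which fell from 236 ± 33.9 to 13.9 ± 5.51.

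Genes with the largest changes between 3 and 18 DAS in rice included RD22 (Os10g0409400), a BURP domain gene found by the pectin list, which rose from 15.6 ± 17.6 to 4268 ± 3581. OsAsr2 (Os01g0963600), an abscisic stress-ripening gene by its symbol, rose from 0.23 ± 0.291 to 1097 ± 572. The lipid transfer protein gene OsLTP1.2 (Os01g0822900) fell from 1300 ± 519 to 0.299 ± 0.336 (log2 -9.93 ± 0.57, limma adjusted p = 2.51e-11). Of 13 sugar transporter genes 8 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.0296, adjusted p = 0.193 with an estimated correlation), and OsSUT1 (Os03g0170900), a sucrose carrier, rose from 9.09 ± 3.03 to 67.7 ± 38.3. In all 8991 genes were higher and 10191 lower at 18 than at 3 DAS, and 5743 were higher and 6359 lower at 18 than at 9 DAS. With only the 2 stages fitted 3474 genes were higher at 18 than at 9 DAS. On the FPKM as deposited the share of calls that were higher went from 46.9% to 36.2% at 18 against 3 DAS (median shift -0.357) and from 47.5% to 76.4% at 18 against 9 DAS (median shift 0.534), with 11090 genes higher and 3426 lower. Clock genes differed between libraries of these stages: the morning gene LHY (Os08g0157600) stood at 2252 in the 9 DAS library R1 against 261 to 289 in the other 3, and at 161 and 140 in the 18 DAS libraries R3 and R4 against 1178 and 1546 in R5 and R6. The light-harvesting scores were 7.849 and 7.264 in R3 and R4 and 5.83 and 5.304 in R5 and R6.

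The genes that place and control callose at plasmodesmata were followed because the lines mark these channels. Callose, a beta-1,3-glucan, narrows the channel when it is laid down at the neck. In rice all 6 plasmodesmata callose-binding protein (PDCB) genes fell between 3 and 18 DAS (6 adjusted over the list alone), with a median log2 change of -4.09 (camera adjusted p = 0.000367, adjusted p = 0.0953 with an estimated correlation). Between 7 and 9 DAS all 6 fell (6 adjusted over the list alone) by a median of -3.06 (camera adjusted p = 0.00314, adjusted p = 0.0901 with an estimated correlation). Between 9 and 18 DAS 4 fell further (4 adjusted over the list alone), with a median of -1.01 over the 6, and camera did not call the list (adjusted p = 0.061). Os05g0512600 (chromosome 5, 25399448 to 25401593), with a mucin-2-like protein as its best deposited match and PDCB 3 as the next, fell from 275 ± 40.8 at 3 DAS to 1.52 ± 0.401 at 9 DAS and 0.832 ± 0.293 at 18 DAS (log2 -7.24 ± 0.15, limma adjusted p = 6.88e-17). Os07g0600700 (chromosome 7, 24505215 to 24508630) fell from 62.1 ± 5.86 to 11.1 ± 3.16 at 9 DAS and 1.19 ± 0.475 at 18 DAS. Os03g0756300 (chromosome 3, 31216563 to 31218820) fell from 95.0 ± 13.7 to 2.77 ± 0.772 at 9 DAS, and Os03g0421800 (chromosome 3, 17569815 to 17572007) from 28.3 ± 5.07 to 6.65 ± 0.74.

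Of 16 callose synthase genes 3 rose and 3 fell at 18 against 3 DAS (3 and 3 adjusted over the list alone), and camera did not call the list (adjusted p = 0.745). The callose synthase 9 gene (Os03g0119500) fell from 33.8 ± 11.5 to 17.6 ± 3.07 (log2 -0.86 ± 0.23, limma adjusted p = 0.00269), while OsGSL1 (Os06g0112800) stood at 81.4 ± 25.5 and 66.6 ± 6.38 (log2 -0.24 ± 0.29, limma adjusted p = 0.469). Of 49 beta-1,3-glucanase genes, which include callose-degrading enzymes, 17 rose and 2 fell at 5 against 3 DAS (18 and 3 adjusted over the list alone; camera adjusted p = 0.00531, adjusted p = 0.215 with an estimated correlation). At 7 against 3 DAS 24 rose and 6 fell (26 and 6 adjusted over the list alone; camera adjusted p = 0.00136, adjusted p = 0.173 with an estimated correlation). At 18 against 3 DAS 11 rose and 23 fell (11 and 23 adjusted over the list alone), and camera did not call the list (adjusted p = 0.315). Between 3 and 18 DAS, Gns10 (Os01g0713200) rose from 20.6 ± 25.0 to 453 ± 198, Gns9 (Os02g0771700) fell from 150 ± 16.5 to 4.98 ± 5.38, and Gns11 (Os07g0539100) fell from 66.9 ± 43.8 to 6.54 ± 1.77. Os10g0370500 stood at 68.3 ± 29.8 and 68.3 ± 38.4 (log2 -0.07 ± 0.41, limma adjusted p = 0.889). Of 15 genes of the MCTP and synaptotagmin lists, proteins that tether the endoplasmic reticulum to the plasma membrane, 4 rose and 6 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.494). OsNTMC2T1.1 (Os02g0448400) fell from 41.9 ± 8.92 to 18.0 ± 4.32.

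**Figure D2:**
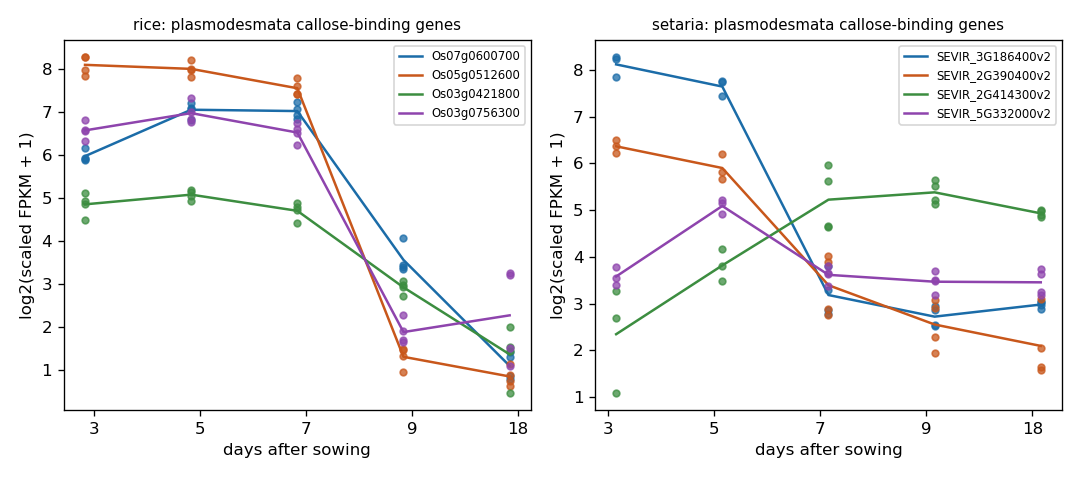
Log2(scaled FPKM + 1) (vertical axes) of the 4 most abundant plasmodesmata callose-binding protein genes of rice (left) and setaria (right) by stage in days after sowing (horizontal axes, stages evenly spaced). Each point is a library and each line joins stage means, and in setaria SEVIR_2G414300v2 went from a mean of 5.05 to 29.5 scaled FPKM between 3 and 18 DAS while SEVIR_3G186400v2 went from 280 to 6.89.

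The setaria comparison of 5 with 3 DAS showed a fall of cell division genes and a rise of part of the photosynthesis genes. Of 24 DNA replication genes 21 fell (22 adjusted over the list alone; camera adjusted p = 8.37e-12, adjusted p = 0.24 with an estimated correlation), and of 17 mitotic cyclin and CDKB genes 12 fell (13 adjusted over the list alone; camera adjusted p = 5.41e-07, adjusted p = 0.24 with an estimated correlation). The CDKB2-1 gene (SEVIR_6G215250v2) fell from 63.3 ± 14.7 to 23.6 ± 7.57 (log2 -1.41 ± 0.45, limma adjusted p = 0.0304). Of 18 photosystem subunit genes 6 rose (9 adjusted over the list alone; camera adjusted p = 3.26e-05, adjusted p = 0.599 with an estimated correlation), and of 26 Calvin cycle genes 11 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 9.72e-05, adjusted p = 0.519 with an estimated correlation). Of 18 light-harvesting genes 3 rose (3 adjusted over the list alone; camera adjusted p = 0.0174, adjusted p = 0.758 with an estimated correlation). Of 15 chlorophyll biosynthesis genes 0 rose and 1 fell (0 and 0 adjusted over the list alone), and camera did not call the list (adjusted p = 0.726). The 3 DAS library R4 stood apart, with a photosystem score of 7.165 against 8.269 and 8.368 in R1 and R2 and a light-harvesting score of 7.91 against 9.548 and 9.654. Phosphoenolpyruvate carboxylase (SEVIR_4G143500v2), the first enzyme of the C4 cycle, rose from 743 ± 506 to 5941 ± 1935 (log2 3.23 ± 0.86, limma adjusted p = 0.0123). The chloroplast NADP-malic enzyme gene (SEVIR_5G132500v2), which releases carbon dioxide in bundle sheath cells, rose from 263 ± 140 to 1310 ± 264 (log2 2.45 ± 0.54, limma adjusted p = 0.00418).

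Further genes that rose were SEVIR_4G184900v2, a polygalacturonase 1 beta-like gene, from 2.46 ± 3.87 to 80.7 ± 60.3, and SEVIR_2G046900v2, described as a myb-like protein X, from 35.1 ± 10.8 to 1991 ± 2315. The tyrosine decarboxylase 1 gene (SEVIR_8G133600v2) fell from 17.6 ± 8.99 and was listed at 0 in the 3 libraries at 5 DAS. The chitinase 11 gene (SEVIR_9G555700v2) fell from 66.4 ± 50.7 to 2.39 ± 1.44. Of 24 seed storage and late embryogenesis genes, a list of seed tissue, 13 rose (14 adjusted over the list alone; camera adjusted p = 2.06e-05, adjusted p = 0.26 with an estimated correlation). In all 2780 genes were higher and 3310 lower. Without the 3 DAS library R4 these counts were 1268 and 1624, without the 3 DAS library R1 2132 were lower, without the 5 DAS library R8 1738 were higher, and on the FPKM as deposited the share that were higher went from 45.6% to 32.4% (median shift -0.221). The phosphoenolpyruvate carboxylase call was lost without the 3 DAS library R4 (log2 2.58) or the 5 DAS library R8 (log2 2.98), and the CDKB2-1 call without the 3 DAS library R1 or R4 or the 5 DAS library R4 or R6 (log2 -1.41, -1.26, -1.15 and -1.46) and with a pseudocount of 0.1 (log2 -1.45).

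By 7 DAS most proliferation and cytosolic ribosome genes of setaria leaves had fallen. The cyclin, DNA replication and histone lists fell almost throughout: 15 of 17, 23 of 24 and 20 of 23 genes were lower than at 3 DAS (15, 23 and 20 adjusted over the list alone). Their camera adjusted p were 1.19e-07, 3.12e-11 and 1.46e-06, and all 3 calls were lost, at adjusted p = 0.24, adjusted p = 0.24 and adjusted p = 0.415 with an estimated correlation. A histone H2A gene (SEVIR_9G453900v2) fell from 760 ± 151 to 0.204 ± 0.164 and the PCNA gene (SEVIR_1G363500v2) from 88.2 ± 21.5 to 3.48 ± 2.42 (log2 -4.45 ± 0.44, limma adjusted p = 2.95e-07). The CDKB2-1 gene (SEVIR_6G215250v2) reached 1.15 ± 1.38 (log2 -5.12 ± 0.42). Of 131 cytosolic ribosomal protein genes 121 fell and 4 rose (121 and 4 adjusted over the list alone; camera adjusted p = 1.87e-19, adjusted p = 0.502 with an estimated correlation), and the L36-3-like gene (SEVIR_3G222100v2) fell from 1797 ± 27.6 to 382 ± 128. Of 32 expansin genes 22 fell and 1 rose (23 and 2 adjusted over the list alone; camera adjusted p = 1.56e-05, adjusted p = 0.24 with an estimated correlation). Of 65 pectin modification genes 6 rose and 35 fell between 5 and 7 DAS (7 and 36 adjusted over the list alone; camera adjusted p = 0.000213), a call that held with an estimated correlation (adjusted p = 0.04). A defensin gene (SEVIR_1G247000v2) fell from 739 ± 42.8 to 0.22 ± 0.193.

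A SWEET13 gene (SEVIR_3G333000v2), a sucrose efflux carrier of the leaf, rose from 9.41 ± 11.5 to 2409 ± 385 at 7 DAS (log2 8.54 ± 0.63, limma adjusted p = 8.57e-09). Of all 19 sugar transporter genes 8 rose and 4 fell (8 and 4 adjusted over the list alone), and camera did not call the list (adjusted p = 0.203). A metallothionein gene (SEVIR_5G140200v2) rose from 27.1 ± 32.5 to 7535 ± 1808. Of 24 photorespiration genes 17 rose and 3 fell (17 and 3 adjusted over the list alone; camera adjusted p = 0.000357, adjusted p = 0.24 with an estimated correlation). In all 5613 genes were higher and 7480 lower at 7 than at 3 DAS, and 4090 were higher and 6255 lower at 7 than at 5 DAS. The 4 libraries at 7 DAS stood apart in several lists: R1 and R3 had light-harvesting scores of 10.621 and 10.398 and secondary wall cellulose synthase scores of 5.487 and 5.384, against 4.495 and 5.836, and 0.272 and 0.513, in R9 and R10. The morning clock gene CCA1 (SEVIR_6G053100v2) stood at 2482 and 2559 in R1 and R3 and at 37.3 and 40.1 in R9 and R10.

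At 9 DAS proliferation genes of setaria leaves stayed low and plastid ribosome genes were lower than at 3 DAS. Of 18 light-harvesting genes 12 fell and 3 rose (13 and 3 adjusted over the list alone), though camera did not call the list (adjusted p = 0.239). The 9 DAS libraries stood apart in this list, with scores of 6.394 and 6.835 in R1 and R4 and of 3.929 and 4.958 in R10 and R12, and the clock gene CCA1 (SEVIR_6G053100v2) stood at 1091 and 1148 against 30.6 and 49.7 in the same libraries. The gene SEVIR_4G229200v2 of this list stood at 1579 ± 1098 at 3 DAS and 200 ± 233 at 9 DAS (log2 -3.72 ± 1.59, limma adjusted p = 0.0535), a difference that missed the threshold. It passed without the 3 DAS library R4 (log2 -4.54), the 9 DAS library R1 or R4 (log2 -4.18 and -4.56) or any one of the 7 DAS libraries (log2 -3.72), on the FPKM as deposited (log2 -3.63) and with only the 2 stages fitted. Of 37 plastid ribosomal protein genes 34 fell (34 adjusted over the list alone; camera adjusted p = 2.2e-06, adjusted p = 0.549 with an estimated correlation). All 3 secondary wall cellulose synthases fell (3 adjusted over the list alone), with one (SEVIR_9G227000v2) going from 17.1 ± 8.35 to 0.241 ± 0.03, while camera did not call the list (adjusted p = 0.333). An abscisic stress-ripening gene (SEVIR_5G469900v2) rose from 1.56 ± 2.04 to 854 ± 218, and a pathogenesis-related PRB1-3-like gene (SEVIR_2G029300v2) from 0.127 ± 0.017 to 691 ± 386. In all 6546 genes were higher and 7690 lower at 9 than at 3 DAS.

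Between 7 and 9 DAS limma called only 2 setaria genes higher and 5 lower, with 4599 genes at an unadjusted p under 0.05. These 7 genes were chosen after their values were seen. The ureide permease 1-like gene (SEVIR_3G373966v2; log2 -3.44), SEVIR_5G252100v2 (log2 -4.81), an inorganic pyrophosphatase 2 gene (SEVIR_1G031500v2; log2 -1.42), a peroxidase 45-like gene (SEVIR_4G259900v2; log2 -0.99) and BGI_novel_G000760, a gene model described as TAP46 (log2 -0.88), were lower. SEVIR_1G031800v2 (log2 1.18) and SEVIR_9G472900v2 (log2 0.78) were higher. Without the 7 DAS libraries R9 and R10 3156 genes were higher and 3295 lower, and without the 7 DAS libraries R1 and R3 limma called 0 and 0. Without the 7 DAS library R9 alone the counts were 1120 and 1451, and without the 9 DAS library R1 69 and 13. With only the 2 stages fitted limma called 0 and 0, so all 7 calls were lost. With each of the 18 setaria libraries left out in turn, the calls were lost 4 times for SEVIR_3G373966v2, 5 times for SEVIR_4G259900v2, 7 times for SEVIR_9G472900v2, 8 times for SEVIR_5G252100v2, 12 times for SEVIR_1G031500v2 and 15 times for SEVIR_1G031800v2. For BGI_novel_G000760, which passed the filter in 15 of these fits, the call was lost 11 times. Camera called light-harvesting genes lower at 9 than at 7 DAS (median log2 -2.74, adjusted p = 1.93e-07), with 0 of 18 genes called singly (0 adjusted over the list alone; adjusted p = 0.388 with an estimated correlation). Only the 7 DAS libraries R1 and R3, at scores of 10.621 and 10.398, lay above the 9 DAS libraries (3.929 to 6.835), while R9 and R10, at 4.495 and 5.836, lay within their range.

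At 18 DAS several core genes of the C4 cycle and a sucrose transporter gene stood above 3 DAS in setaria leaves. Clock genes differed between these stages too. CCA1 (SEVIR_6G053100v2) stood at 77.4 to 88.2 at 3 DAS and 699 to 1727 at 18 DAS, and PRR1 (SEVIR_1G241000v2) at 8.14 to 10.85 and 15.5 to 87.55. Without hours of collection, stage and time of day cannot be told apart for genes that follow the clock. Phosphoenolpyruvate carboxylase (SEVIR_4G143500v2, chromosome 4, 27245917 to 27254607) rose from 743 ± 506 to 9822 ± 4541 (log2 3.81 ± 0.80, limma adjusted p = 0.000684). A chloroplast carbonic anhydrase gene (SEVIR_5G247800v2) rose from 730 ± 664 to 7036 ± 3666 (log2 3.56 ± 0.90, limma adjusted p = 0.00287), the NADP-malate dehydrogenase gene (SEVIR_6G256400v2) from 169 ± 65.2 to 813 ± 347, and the NADP-malic enzyme gene (SEVIR_5G132500v2) from 263 ± 140 to 2807 ± 579. The 18 DAS library R3 stood apart, with carbonic anhydrase at 1595 against 8097 to 9231 and NADP-malate dehydrogenase at 299 against 908 to 1034 in the other libraries. Of all 35 C4 cycle genes 14 rose and 8 fell (15 and 8 adjusted over the list alone), and camera did not call the list (adjusted p = 0.428). In rice 25 of 46 members of this list rose and 13 fell between 3 and 18 DAS (25 and 13 adjusted over the list alone; camera adjusted p = 0.0783). The rice phosphoenolpyruvate carboxylase gene PEPC-1 (Os02g0244700) went from 81.4 ± 7.62 to 114 ± 30.4 (log2 0.45 ± 0.15, limma adjusted p = 0.0111), a call that was lost on the FPKM as deposited (log2 0.02), with only the 2 stages fitted (log2 0.45) and without the 18 DAS libraries R3 and R4 (log2 0.12).

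The sucrose transporter gene SUT1 (SEVIR_9G528600v2), which loads sucrose into the phloem, rose from 17.2 ± 9.78 to 215 ± 28.4 (log2 3.71 ± 0.33, limma adjusted p = 6.98e-08). The SWEET13 gene (SEVIR_3G333000v2) stood at 1462 ± 770 (log2 7.72 ± 0.63). Of all 19 sugar transporter genes 7 rose and 6 fell (7 and 6 adjusted over the list alone), and camera did not call the list (adjusted p = 0.402). An endochitinase A gene (SEVIR_7G158600v2) rose from 0.141 ± 0.211 to 284 ± 98.4. Cell cycle lists stayed low: 15 of 17 cyclin and CDKB genes were lower than at 3 DAS (15 adjusted over the list alone; camera adjusted p = 3.31e-08, adjusted p = 0.24 with an estimated correlation). In all 6411 genes were higher and 7290 lower at 18 than at 3 DAS, and 1173 were higher and 1151 lower at 18 than at 9 DAS. The latter counts were 2690 and 2029 without the 18 DAS library R3, and 386 to 682 higher and 428 to 738 lower without one of the 18 DAS libraries R6, R8 and R11 or the 9 DAS libraries R4 and R12. With only the 2 stages fitted they were 457 and 551. On the FPKM as deposited 664 genes were higher and the share that were higher went from 50.5% to 33.7% (median shift -0.157).

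The plasmodesmata genes of setaria split in direction. Of 6 tested PDCB genes 2 rose and 3 fell between 3 and 18 DAS (2 and 3 adjusted over the list alone), and camera did not call the list (adjusted p = 0.594). SEVIR_3G186400v2 (chromosome 3, 13356498 to 13359294) fell from 280 ± 43.4 to 6.89 ± 0.356 (log2 -5.14 ± 0.22, limma adjusted p = 8.57e-12), and SEVIR_2G390400v2 (chromosome 2, 43759287 to 43762987) fell from 81.7 ± 7.87 to 3.70 ± 2.61 (log2 -4.27 ± 0.39, limma adjusted p = 1.08e-07). SEVIR_2G414300v2 (chromosome 2, 45178984 to 45180984) rose from 5.05 ± 3.75 to 29.5 ± 1.47 (log2 2.59 ± 0.41, limma adjusted p = 5.13e-05). SEVIR_5G332000v2 stood at 11 ± 1.66 and 10.1 ± 2.15 (log2 -0.12 ± 0.18, limma adjusted p = 0.577). The plasmodesmata-located protein 8-like gene (SEVIR_7G192100v2, chromosome 7, 25064600 to 25067837) rose from 1.24 ± 0.464 to 9.41 ± 0.78 (log2 2.23 ± 0.30, limma adjusted p = 1.03e-05). The 3-like gene (SEVIR_9G550100v2) stood at 13.0 ± 1.55 and 14.2 ± 3.98 (log2 0.08 ± 0.23, limma adjusted p = 0.779). The description search found no gene so described in rice, which rests on the wording of the descriptions and does not show that rice lacks such genes.

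Of 10 callose synthase genes 1 rose and 4 fell in setaria (1 and 4 adjusted over the list alone; camera adjusted p = 0.644). A callose synthase 3 gene (SEVIR_9G560600v2) rose from 2.56 ± 1.20 to 15.3 ± 0.839 (log2 2.25 ± 0.26, limma adjusted p = 1.94e-06). Another (SEVIR_1G386100v2) fell from 74.8 ± 8.70 to 50.2 ± 7.83 (log2 -0.57 ± 0.21, limma adjusted p = 0.0247), a call lost on the FPKM as deposited (log2 -0.66) and without the 3 DAS library R2 or R4 or the 18 DAS library R8 or R11 (log2 -0.60, -0.44, -0.54 and -0.50). Of 48 beta-1,3-glucanase genes 16 rose and 19 fell (16 and 20 adjusted over the list alone; camera adjusted p = 0.543), among them SEVIR_9G391800v2, which rose from 10.6 ± 5.36 to 83.3 ± 35.4, and SEVIR_8G260300v2, which fell from 138 ± 22.6 to 34.9 ± 12.1. An FT-interacting protein 1 gene (SEVIR_2G326600v2) of the MCTP list rose from 14.3 ± 5.66 to 53.3 ± 6.53.

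The last comparison asked whether the change from 3 to 18 DAS differed between the species, with the setaria change minus the rice change as the tested difference. The PDCB list fell less in setaria than in rice: its mean log2 value changed by -4.40 in rice and by -1.43 in setaria, a difference of 2.98 ± 0.20 (SE; limma adjusted p = 5.1e-14). Photosynthesis lists rose less or fell in setaria, but they started from higher levels there. At 3 DAS the mean log2 value of light-harvesting genes was 9.037 in setaria and 4.758 in rice. That of photosystem subunits was 7.934 and 3.127, and that of chlorophyll biosynthesis 7.122 and 4.57. At 18 DAS the means of these lists still stood higher in setaria, at 7.895 against 6.562, 8.122 against 6.14 and 5.555 against 4.677 in that order. These differences in level were not tested. The light-harvesting scores of single libraries overlapped at 18 DAS, at 5.304 to 7.849 in rice and 6.885 to 8.98 in setaria. Light-harvesting genes changed by 1.80 in rice and -1.14 in setaria (difference -2.95 ± 1.26, limma adjusted p = 0.0403), a call that was lost with the median over members in place of the mean (limma adjusted p = 0.0808). Photosystem subunits changed by 3.01 and 0.19 (difference -2.83 ± 0.54, limma adjusted p = 3.86e-05), and chlorophyll biosynthesis by 0.11 and -1.57 (difference -1.68 ± 0.42, limma adjusted p = 0.000779). Primary wall cellulose synthases fell further in rice (-2.82) than in setaria (-1.18), a difference of 1.64 ± 0.23 (limma adjusted p = 2.51e-07). The C4 cycle list changed by 1.27 in rice and 0.71 in setaria (difference -0.57 ± 0.18, limma adjusted p = 0.00754, and -0.32 on the FPKM as deposited). This list is a description search whose members rose and fell in both species. Its mean therefore does not tell in which species the C4 cycle itself rose more. Lists of mitotic cyclins and of DNA replication fell further in setaria, with differences of -0.95 ± 0.13 and -0.89 ± 0.14, the latter -0.58 with the median over members. Expansins changed by -2.02 and -2.29, and the difference of -0.27 ± 0.22 missed the threshold (limma adjusted p = 0.298). In all 22 of 33 lists and 1715 of 3888 KEGG numbers differed, 829 with a higher and 886 with a lower change in setaria. Members of a list are not matched between the species, and among the 1307 numbers with exactly 1 gene in each species 536 differed.

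Set beside the authors' deposited tables, 99.9% to 100% of the genes called here against 3 DAS had the same sign there. Between 90.9% and 95.9% of the rice calls and between 87.3% and 96.8% of the setaria calls also had an adjusted p under 0.05 in the authors' deposited tables. These shares cover only genes called here, from the same libraries. At 5 against 3 DAS the authors' tables held 6026 higher and 5651 lower rice genes at that threshold (4417 and 3066 here). For setaria they held 5014 higher and 3904 lower (2780 and 3310 here), so the balance of directions differed.

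**Figure D3:**
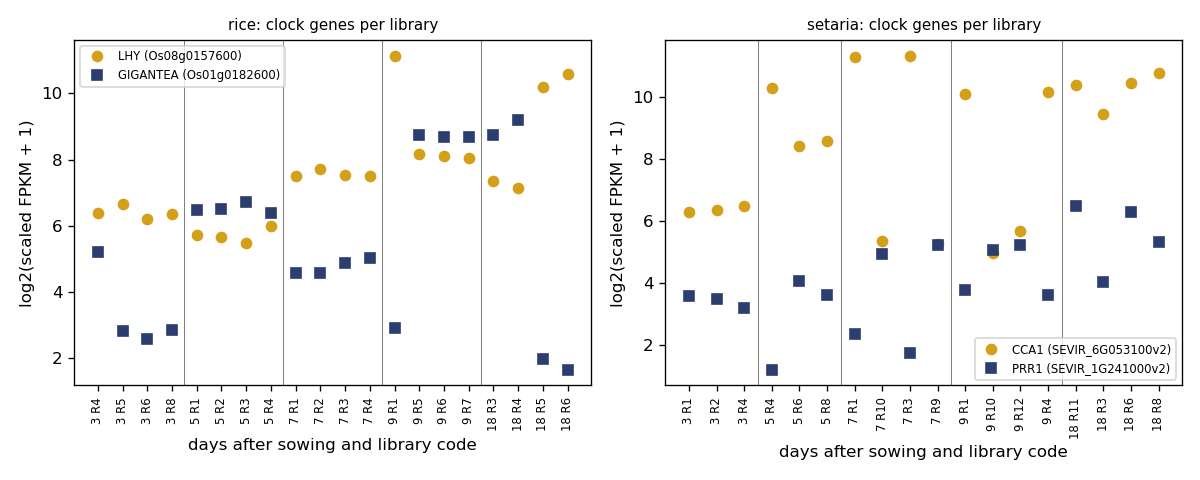
Log2(scaled FPKM + 1) (vertical axes) of a morning and an evening clock gene in each library (horizontal axes, days after sowing and library code) of rice (left, LHY and GIGANTEA) and setaria (right, CCA1 and PRR1). Circles are the morning gene and squares the evening gene, vertical lines part the stages, and in the setaria 7 DAS library R9 both markers overlap, with CCA1 at 37.3 and PRR1 at 36.0 scaled FPKM.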

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

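The tests on clock genes, on depth, on the setaria libraries at 7 DAS and on redrawn species were chosen only after the result was seen, while those on regrouped libraries and on abundant rice genes were fixed before. Of 152 groups of 4 libraries tested, 19 had a library far from the others by Dixon's ratio (the gap to the nearest library over the whole range, at its 95% critical value), and chance flags about 1 in 20 groups.

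The first pattern was that clock genes differed between libraries of one stage, such as LHY (Os08g0157600) and GIGANTEA (Os01g0182600) in rice at 9 DAS, where R1 stood at 2252 and 6.46 and the other libraries at 261 to 289 and 406 to 429. The morning gene and the evening gene PRR1 (Os02g0618200 in rice, SEVIR_1G241000v2 in setaria) went opposite ways over the libraries in 8 of 10 stages, which fits collection at different times of day, although an exact two-sided sign test gave p = 0.109. The relative depths differed by at most 1.142-fold within a species. The search for them allowed only limited differences between pairs of libraries, so this test cannot decide on depth. No hour of collection was given, so time of day may be the source but stays a hypothesis, and no biological explanation was tested. Clock genes also differed between stages, such as LHY in rice, at 73.2 to 99.2 at 3 DAS and 261 to 2252 at 9 DAS. For genes that follow the clock, stage and time of day therefore cannot be told apart in the stage comparisons.

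The second pattern was the gap at 7 DAS in setaria between the libraries R1 and R3 and the libraries R9 and R10, of 4.871 in the secondary wall cellulose synthase score and 4.562 in the light-harvesting score. Time of day alone could not be tested with the wall genes, since their score spanned only 0.08 over the libraries at 9 DAS, where these genes were near 0, while the light-harvesting score spanned 2.906 there. A swap between 7 and 9 DAS is argued against, since 0 of the 4 libraries at 9 DAS lay closer to R1 and R3 of 7 DAS than to the other libraries at 9 DAS. One wrong label cannot give a gap of 2 libraries against 2. Wrong labels on both libraries of a pair and time of day stay open, and no biological explanation was tested.

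The third pattern was the shift of the median rice gene between 3 and 9 DAS on the FPKM as deposited, by -0.662 against the value after scaling. The 50 most abundant genes held 36.1% to 40.9% of all FPKM at 9 DAS and 5.6% to 7.6% at 3 DAS. Without them a shift of -0.425 was left, so a few genes taking a larger share of the FPKM at 9 DAS may account for part of it, and the test did not decide. The relative depth at 9 over 3 DAS was 1.008, but large differences lay outside the search, so this does not decide on depth.

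The change from 3 to 18 DAS differed between rice and setaria for 1715 KEGG numbers and 22 lists. As the setaria change minus the rice change in mean log2 value, the lists with a positive difference were PDCB genes at 2.975, alpha-amylases at 2.871, primary wall cellulose synthases at 1.64, seed storage and late embryogenesis genes at 1.275, remorins at 1.083, KNOX genes at 0.722 and reticulons at 0.682. Those with a negative difference were light-harvesting genes at -2.947, photosystem subunits at -2.825, chlorophyll biosynthesis at -1.675, plastid ribosomal proteins at -1.654, the Calvin cycle at -1.316, photorespiration at -1.266, sugar transporters at -1.173, lignin biosynthesis at -1.023, mitotic cyclins and CDKB at -0.947, DNA replication at -0.893, callose synthases at -0.716, the C4 cycle at -0.567, wax and cutin at -0.398, MCTP and synaptotagmin genes at -0.34 and pectin modification at -0.201. With the median over members in place of the mean the calls were lost for light-harvesting genes (limma adjusted p = 0.0808), wax and cutin (0.077) and MCTP and synaptotagmin genes (-0.20, 0.761), and calls were gained for aquaporins (-0.70, 0.0405) and senescence (-0.74, 0.0364). Differences that then moved by over 1.5 times and stayed called were those of KNOX genes (2.94), sugar transporters (-2.39), the Calvin cycle (-2.31), lignin biosynthesis (-1.71), callose synthases (-1.45), pectin modification (-0.625), photorespiration (-0.58) and DNA replication (-0.58). On the FPKM as deposited those of callose synthases (-0.44), the C4 cycle (-0.32), wax and cutin (-0.18) and MCTP and synaptotagmin genes (-0.08) shrank by over 1.5 times, and that of pectin modification turned to 0.02.

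A fit of the 3 and 18 DAS libraries alone called 1545 KEGG numbers and 21 lists. Stage redrawn within each species 100 times gave at most 1025 and 13, but this also removes the change that both species share, so it says nothing about chance in the difference between them. Species was therefore redrawn within each stage, on what the fit without the difference left over. Of 100 such splits (the real one included), 1 reached the real value for the KEGG numbers, with at most 789 in the others. The real count thus stood above every redrawn one. Redrawn labels still called many numbers, so chance is not excluded for the single calls behind that count. For the lists 1 also reached the real value, but the others called up to 17. Redrawn labels thus called many lists, so the count of lists does not exclude chance. Each species was 1 line without known hours of collection, so neither test tells a species effect from other differences between the libraries.

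Single libraries stood far from the others of their stage in these rice genes. At 3 DAS, OsAsr2 (Os01g0963600) was 0.66 in R5 (ratio 0.891), OsENOD93 (Os06g0141600) 171 in R6 (ratio 0.885), the PDCB gene Os07g0600700 70.9 in R8 (ratio 0.875), GLP8-4 (Os08g0189300) 17.7 in R6 (ratio 0.948) and OsBURP17 (Os11g0170900) 1.37 in R6 (ratio 0.868). At 5 DAS, pdc1 (Os05g0469600) was 8.38 in R2 (ratio 0.936), and the summed FPKM of the libraries had a ratio of 0.87. At 9 DAS, R1 had the lowest LHCB (Os03g0592500) value, 11432 (ratio 0.916), and the highest of OsPIP2 (Os09g0541000), 1185 (ratio 0.88), and of OsRcaII (Os11g0707000), 32410 (ratio 0.903), while Os07g0600700 was 15.8 in R7 (ratio 0.89). At 18 DAS, Gns11 (Os07g0539100) was 9.18 in R5 (ratio 0.908).

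In setaria at 18 DAS, R3 had the lowest carbonic anhydrase (SEVIR_5G247800v2) value, 1595 (ratio 0.851), the lowest NADP-malate dehydrogenase (SEVIR_6G256400v2) value, 299 (ratio 0.8293), and the highest SWEET13 (SEVIR_3G333000v2) value, 2617 (ratio 0.962). At 7 DAS, SEVIR_1G031500v2 was 5.3 in R1 (ratio 0.941) and SEVIR_9G472900v2 was 0.16 in R10 and listed at 0 in the others (ratio 1.0). At 9 DAS, SEVIR_3G373966v2 was 0.15 in R12 and BGI_novel_G000760 0.25 in R4, and both were listed at 0 in the other libraries (ratio 1.0 each).

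Every regrouping of the libraries of both stages was tested with only those stages in the fit. Mixed groups carry the stage difference in their spread, which lowers their counts. A share of 1 in 35 was also not adjusted over comparisons that share libraries, so it does not exclude chance. For genes called, some comparisons had 1 of 35 regroupings, the real one, that reached the real count. In rice this held for 5 against 3 DAS (10262, highest other 8), 7 against 3 (12357 and 0), 9 against 3 (19235 and 1), 18 against 3 (16581 and 0), 7 against 5 (5099 and 1911), 9 against 7 (19142 and 0) and 18 against 9 DAS (7847 and 0). In setaria it held for 7 against 3 (12398 and 0), 9 against 3 (14744 and 233), 18 against 3 (14314 and 6584, with R3 of 18 DAS set among the 3 DAS libraries), 7 against 5 (7797 and 3) and 18 against 9 DAS (1008 and 98). The 10 regroupings of setaria 5 against 3 DAS were too few for a share under 0.05 (real 8052, highest other 0). For rice lists at 18 against 3 DAS the real grouping called 19, but a regrouping that mixed both stages called 18. The count of lists hardly told the stages from mixed libraries, so it does not exclude chance. For setaria lists at 18 against 3 DAS chance cannot be excluded, as 14 of 35 regroupings called at least the real 13, with up to 16. For setaria 9 against 7 DAS the real count was 0, which all 35 regroupings reach by definition, so the comparison says nothing about chance. There R1 and R4 of 9 DAS set with R1 and R3 of 7 DAS against the rest called 857, which points to a structure of the samples. The clock gene CCA1 (SEVIR_6G053100v2) stood at 1091 to 2559 in the former libraries and at 30.6 to 49.7 in the rest.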

How the results depend on the processing

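A pseudocount of 0.1, the FPKM as deposited, RLE scaling of the lists, the replicate block, the list scores with single libraries left out and the left-out pairs of libraries were chosen only after the result was seen. The direction of every named gene that was called and followed through the alternatives was kept under each alternative run. The rice genes of the alpha-amylase search named at 5 against 3 DAS were not followed in this way. RLE scaling in place of trimmed means left the 31 tested counts within 1.5 times their value. A pseudocount of 0.1 gave 391 rice genes lower at 7 than at 5 DAS, and 9 higher and 11 lower setaria genes at 9 than at 7 DAS. On the FPKM as deposited, 4616 rice genes were lower at 5 than at 3 DAS, 5500 higher at 9 than at 3, 4400 higher at 9 than at 7, and 11090 higher and 3426 lower at 18 than at 9 DAS, while 8 setaria genes were higher at 9 than at 7 and 664 at 18 than at 9 DAS. By construction, no factor then removes the shift of the median gene. With only the 2 stages in the fit 2925 rice genes were higher and 2174 lower at 7 than at 5 DAS, and 3474 higher at 18 than at 9 DAS. In setaria limma then called 0 higher and 0 lower at 9 against 7 DAS, where 4599 had an unadjusted p under 0.05 with all stages fitted, and 457 higher and 551 lower at 18 against 9 DAS. Without a filter 5 setaria genes were higher at 9 than at 7 DAS, and with the stricter filter 0 higher and 3 lower. Without R9 and R10 of 7 DAS the counts were 3156 and 3295, and without R1 and R3 0 and 0. In the 5 comparisons fixed before, lists called with an estimated correlation numbered 3 in rice and 0 in setaria, and with fry 145 and 96. Among KEGG numbers with exactly 1 gene in each species, fewer being tested, 536 differed. For the other settings, those with fewer libraries included, the cause was not tested.

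With each library left out in turn, the counts ranged from 385 to 755 for rice genes lower at 7 than at 5 DAS. In setaria they ranged from 1268 to 3170 higher and 1624 to 3795 lower at 5 against 3 DAS, from 0 to 1120 higher and 0 to 1451 lower at 9 against 7 DAS, and from 386 to 2690 higher and 428 to 2029 lower at 18 against 9 DAS. Over these, named genes stayed on their side of the threshold 1705 times, calls were lost 72 times and gained 7 times. The library codes of the deposited tables match the replicate numbers of the labels only in rice at 5 and 7 DAS. A replicate block by code was fitted for the comparisons whose stages share at least 2 codes, and for the other comparisons no such block could be fitted. Deviations of same-coded libraries from their stage means correlated at -0.566 to 0.141 in rice at 7 and 5 DAS and at -0.02 to 0.129 in rice at 18 and 3 DAS, and not every library correlated best with its own code. Where 2 codes are shared they correlated at -0.001 and -0.078 in rice at 9 and 3 DAS, -0.402 and -0.474 in rice at 18 and 9 DAS, 0.12 and -0.18 in setaria at 9 and 3 DAS, and 0.205 and 0.416 in setaria at 9 and 7 DAS. With 2 of 4 libraries the last cannot show a pairing, so the codes were not taken to pair libraries. The replicate block left 11 counts within 1.5 times their value, among them 960 higher and 484 lower in rice at 7 against 5 DAS, and gave 4 higher in setaria at 9 against 7 DAS. The 49 results of named genes in these fits kept their side of the threshold. The count-based tests (the Wald test of DESeq2 in place of the first choice) were not run because the values are not counts. Depth is unknown, so no counting limit could be set on low values.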

Other observations

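Tests of the list added for cysteine-rich repeat secretory proteins were chosen only after the result was seen. In rice, of 27 senescence and chlorophyll breakdown genes 17 rose and 4 fell between 3 and 18 DAS (17 and 4 adjusted over the list alone; limma's camera adjusted p = 0.00636, adjusted p = 0.0955 with an estimated correlation). One of them, OSA15 (Os05g0148700), went from 15.2 ± 0.987 to 125 ± 65.7. The KNOX homeobox list, regulators of the shoot meristem, held 3 genes that rose and 6 that fell of 9 (3 and 6 adjusted over the list alone; camera adjusted p = 0.372), and Os06g0646600 rose from 4.33 ± 1.42 to 282 ± 48.7 (log2 5.75 ± 0.19, limma adjusted p = 1.27e-14). Of 21 remorins, membrane scaffold proteins, 8 rose and 12 fell (8 and 12 adjusted over the list alone; camera adjusted p = 0.242). OsREM1.5 (Os04g0533300) rose from 47.8 ± 3.12 to 424 ± 296, and OsREM5.1 (Os02g0767000) fell from 51.1 ± 3.91 to 2.01 ± 1.1.

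Of 45 heat shock protein genes of setaria, chaperones, 13 rose between 9 and 18 DAS (21 adjusted over the list alone; camera adjusted p = 3.31e-08, adjusted p = 0.24 with an estimated correlation). Of the 13 genes found by the alpha-amylase search 10 rose and 1 fell between 3 and 18 DAS (10 and 1 adjusted over the list alone; camera adjusted p = 0.00913, adjusted p = 0.248 with an estimated correlation). These held an alpha-amylase/trypsin inhibitor gene (SEVIR_2G376900v2), which rose from 0.757 ± 0.585 to 117 ± 81.3, beside the chloroplast alpha-amylase 3 gene (SEVIR_5G298000v2), which breaks down starch and rose from 5.7 ± 0.395 to 14.4 ± 4.75.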
